A study of Homo sapiens with 8 samples.

How the data were processed

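Chromatin from HuCCT1 cells was cross-linked with formaldehyde, sheared by sonication, precipitated with antibodies against YAP, TAZ, TEAD1, TEAD4 or the HA tag, and made into libraries with a kit for Illumina sequencing, per the labels' protocols. Bowtie2 and the hg19 build are named in the submitters' processing notes, without a version. The peak names in the deposited lists begin with MACS, the name of a peak caller. The caller's version, its threshold and the control library used for each list are not given in the sources used here. Each of the 5 deposited lists belongs to 1 sample with 1 library, so no peaks were pooled over replicates. Each row gives a chromosome, a start, an end, a name and a score, which is the authors' own value for the peak. The scale of the deposited score is not stated. All lists begin at about 80 and several values sit at 3100, which is the highest value in the YAP and TEAD4 lists and is exceeded by some TEAD1 peaks. Scores were therefore compared only within a list, where they were used to rank, split or filter peaks and to compare medians. A difference or ratio of medians is on that unstated scale and is no measure of how much more protein was bound. The authors' processing affects what can be compared: a list can reflect the strength of the precipitation, the depth of its library, its control and its threshold together, so the number of peaks is not a measure of the number of binding sites.

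The peaks in each list were numbered without gaps. The TEAD1 and TEAD4 lists have named columns and their starts were taken as counted from 1. The other lists have no header and their starts were taken as counted from 0, as in BED files, and raised by 1. Starts are therefore uncertain by 1 bp. Coordinates are hg19 as deposited.

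Samples were grouped by their titles, with 1 library per group. The input, IgG and GFP libraries were not analysed here. A pair of peaks counted as shared when at least 1 bp overlapped. For each of the 10 pairs of lists, the number of peaks of the shorter list that overlapped the longer was compared with 10000 circular shifts of the shorter list, each chromosome shifted by its own random distance within the span that the lists cover. This keeps the spacing of peaks. The p-value is one-sided, with a smallest value of 0.0001, and was adjusted by the Benjamini-Hochberg method over the pairs. Scores and widths of TEAD1 and TEAD4 peaks with and without each of 4 other lists were compared by the difference of medians with 100000 permutations over peaks, two-sided. The same test was used in the YAP and HA-YAP5SA lists. Peaks within 12.5 kb of another, centre to centre, were called clustered and compared by Fisher's exact test. Peaks are not replicates, intervals cover counting error only, and the sequencing depth of each library is unknown. Intervals are exact Clopper-Pearson intervals at 95%, and a count of 0 was read as allowing 3 peaks. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and numba 0.67.0, and figures were drawn with matplotlib 3.10.9.

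The position test and the score test were tested on simulated data. Simulated peaks had the widths of HA-YAP5SA peaks and, where not planted, random positions on placed chromosomes. They held no dense runs or scaffold peaks, so the position test was not checked for lists such as YAP and TAZ. In the score test the marked TEAD1 peaks were drawn at random. Lists of 847 peaks with 10, 50 and 95% of peaks planted on TEAD1 gave back 10.9, 50.5 and 95.1% and were called in all 10 simulations each. Lists with no planted peaks were called in 2 of 50. Among 847 TEAD1 peaks, a planted score ratio of 1.5 was called in 20 of 20 simulations, a ratio of 1.1 in 16 of 20 and a ratio of 1 in 6 of 100, at an unadjusted p of 0.05.

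The list overlaps, the score and width tests in the TEAD lists, the partner shares, the cluster test by YAP, their alternatives and the rule for named peaks were fixed before the data were examined. The score deciles, the splits of the YAP and HA-YAP5SA lists, the odds ratios between lists, the cluster splits by HA-YAP5SA and TEAD4, and the dense runs were added afterwards. The peaks named are the 10 with the highest score of each list, given in full for HA-YAP5SA and in part for the others, and the 10 sites with the highest YAP score among those shared by YAP, HA-YAP5SA, TEAD1 and TEAD4. Runs named as examples were chosen after the data were examined. Planned comparisons of peaks with promoters, sequence motifs and gene lists needed an hg19 genome or annotation and were not run. The gene table at hand follows GRCh38, whose coordinates do not apply to these peaks, so no peak was assigned to a gene. Alternatives were a stricter overlap (50% of the shorter peak), centres within 500 bp, peaks within 1 kb, a stricter score threshold, equal numbers of TEAD1 and TEAD4 peaks, local shifts of 50 to 500 kb, chromosomes 1 to 22 and X, other cluster distances and width quintiles. Leaving out dense runs of YAP or TAZ peaks and unplaced scaffolds was added after the data were examined.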

Results

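Chromatin occupancy was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in HuCCT1, a human cholangiocarcinoma (bile duct cancer) cell line. The series held 8 libraries, with 1 library per antibody or control. Peak lists were analysed for 5 of them: YAP, its paralogue TAZ (the product of WWTR1), the DNA-binding factors TEAD1 and TEAD4, and HA-YAP5SA. YAP and TAZ are transcriptional coactivators of the Hippo pathway that do not bind DNA by themselves and reach it mainly through TEAD factors. YAP5SA is a YAP form whose serines targeted by the LATS kinases are replaced by alanine, and here it was precipitated through an HA tag. The libraries titled input, IgG and GFP were read as background in the design and were not analysed here. The title of the GFP library does not say what was precipitated. There were no replicates, so no difference between lists has a replicate check, and the sequencing depth behind each list is unknown. Intervals below are exact 95% binomial intervals and cover counting error over peaks only. Peaks within a library are not independent replicates.

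The lists differed in size and in the shape of their peaks. The TEAD1 list held 38186 peaks with a median width of 552 bp (interquartile range 456 to 663 bp), covering 22208 kb. The TEAD4 list held 12188 peaks with a median width of 352 bp (282 to 441 bp), covering 4644 kb. The HA-YAP5SA list held 847 peaks with a median width of 224 bp (162 to 319 bp). The YAP list held 454 peaks with a median width of 628 bp (282 to 1290 bp), and the TAZ list held 153 peaks with a median width of 785 bp (293 to 1333 bp). The widest YAP peak spanned 51110 bp and the widest HA-YAP5SA peak 2144 bp. Each list started at a peak score of about 80, the lowest values being 80.05 for YAP, 80.08 for HA-YAP5SA, 80.18 for TAZ, and 80 for TEAD1 and TEAD4.

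The first comparison asked whether YAP lies where TEAD factors lie. HA-YAP5SA peaks lay almost always on TEAD sites. Of the 847 HA-YAP5SA peaks, 806 (95.2%, interval 93.5 to 96.5%) overlapped a TEAD1 peak and 783 (92.4%, 90.5 to 94.1%) overlapped a TEAD4 peak. Both TEADs were present at 781 HA-YAP5SA peaks (92.2%, 90.2 to 93.9%), TEAD1 alone at 25, TEAD4 alone at 2 and neither at 39 (4.60%, 3.29 to 6.24%). The centres of HA-YAP5SA peaks lay a median of 70 bp from the nearest TEAD1 centre (interquartile range 35 to 128 bp) and 57 bp from the nearest TEAD4 centre (27 to 103 bp). Circular shifts of the HA-YAP5SA list along its chromosomes gave 9.92 overlaps with TEAD1 on average (95% of shifts 4 to 17) and 2.53 with TEAD4 (0 to 6). No shift reached the observed overlap with either TEAD, so p was 0.0001, the smallest that 10000 shifts can give (adjusted p = 0.00014, one-sided permutation test, Benjamini-Hochberg over 10 pairs of lists).

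Of the 10 HA-YAP5SA peaks with the highest scores, 9 carried both TEADs. The top HA-YAP5SA peak lay on chromosome 14 (hg19 62221732 to 62222489, score 1028). It overlapped the second-ranked TEAD1 peak (62221091 to 62222739, score 3144), a TEAD4 peak with the list's highest score, 3100, which 5 TEAD4 peaks share (62221647 to 62222613) and a YAP peak (62221930 to 62222473, score 924). The next were on chromosome 11 (18284158 to 18284766, score 983), at the start of chromosome 5 (10002 to 11787, score 890), on chromosome 1 (210438953 to 210439502, score 844, and 109045566 to 109046140, score 794), on chromosome 12 (461497 to 462041, score 689) and on chromosome 13 (111137867 to 111138288, score 674). Chromosome 7 (55035003 to 55035551, score 654), chromosome 1 (19378944 to 19379450, score 632) and chromosome 4 (102875061 to 102875570, score 593) completed the top 10. Of these 10 peaks, 6 overlapped a peak of the YAP antibody. The peak at the start of chromosome 5 overlapped neither TEAD. The genes at these positions were not assigned here.

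The antibody against YAP gave peaks that overlapped TEAD at a smaller share. Of its 454 peaks, 92 (20.3%, interval 16.7 to 24.3%) overlapped TEAD1, 84 (18.5%, 15 to 22.4%) overlapped TEAD4 and 54 (11.9%, 9.06 to 15.2%) overlapped HA-YAP5SA. Shifted YAP peaks met TEAD1 7.27 times on average (95% of shifts 2 to 15), TEAD4 2.05 times (0 to 6) and HA-YAP5SA 0.131 times (0 to 1), and the adjusted p was 0.00014 in each case (the same shift permutation test). Among peaks at or above the median score of their lists, these shares were 9.25% with TEAD1, 5.29% with TEAD4 and 3.96% with HA-YAP5SA. This cut both lists of a pair, which leaves fewer peaks to overlap. With the TEAD lists kept whole, 78.4% of the YAP peaks at or above the median score lay on neither TEAD. Neither TEAD was present at 346 YAP peaks (76.2%, 72.0 to 80.1%). YAP peaks with TEAD1 were narrower than those without, with median widths of 248 and 745 bp (adjusted p = 1.8e-05, two-sided permutation test over peaks, 16 tests in the family). Their median score was also lower, 119 against 149 (adjusted p = 0.033, same permutation test). The direction of the score difference turned among dispersed YAP peaks, defined next, to 111 with TEAD1 and 98.9 without (adjusted p = 0.13, same permutation test). There the median widths were 228 and 323 bp (adjusted p = 0.00043, same permutation test).

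Most YAP and TAZ peaks lay in dense runs or on scaffolds that are not placed on the assembled chromosomes. A run was defined, after the lists had been examined, as at least 4 YAP or TAZ peaks with neighbouring centres at most 25 kb apart, and 29 such runs were found. Runs or scaffolds held 320 of the 454 YAP peaks (70.5%, interval 66.1 to 74.6%) and 109 of the 153 TAZ peaks (71.2%, 63.4 to 78.3%). They held 1 of 847 HA-YAP5SA peaks (0.118%, 0.00299 to 0.656%), 58 of 38186 TEAD1 peaks (0.152%) and 25 of 12188 TEAD4 peaks (0.205%). Runs were built from YAP and TAZ peaks, so the higher shares of the YAP and TAZ lists are partly fixed by the definition. The same rule was not applied to the other lists. The run with the most peaks, 53 of YAP and 8 of TAZ, lay on the scaffold gl000199 of chromosome 9 (34297 to 166429). A run on chromosome X (61682072 to 61723527) held 27 YAP and 16 TAZ peaks, a run on chromosome 16 (58555042 to 58633252) held 39 YAP peaks and 1 TAZ peak, and a run on chromosome 4 (49093263 to 49158714) held 25 YAP peaks. YAP and TAZ peaks together covered 91.3% of the chromosome X run and 11.4% of the chromosome 16 run. The 10 highest-scoring YAP peaks were 3320 to 51110 bp wide. Of these 10, 4 lay in runs, 1 overlapped TEAD1, 2 overlapped TEAD4 and none overlapped HA-YAP5SA. The rest fell outside runs, including adjoining peaks on chromosome Y that were too few and too wide to make a run. Those peaks count as dispersed below. The 2 widest lay side by side on chromosome Y (58819364 to 58870473 and 58870601 to 58902580), at 3100, a score that 6 YAP peaks share.

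**Figure D1:**
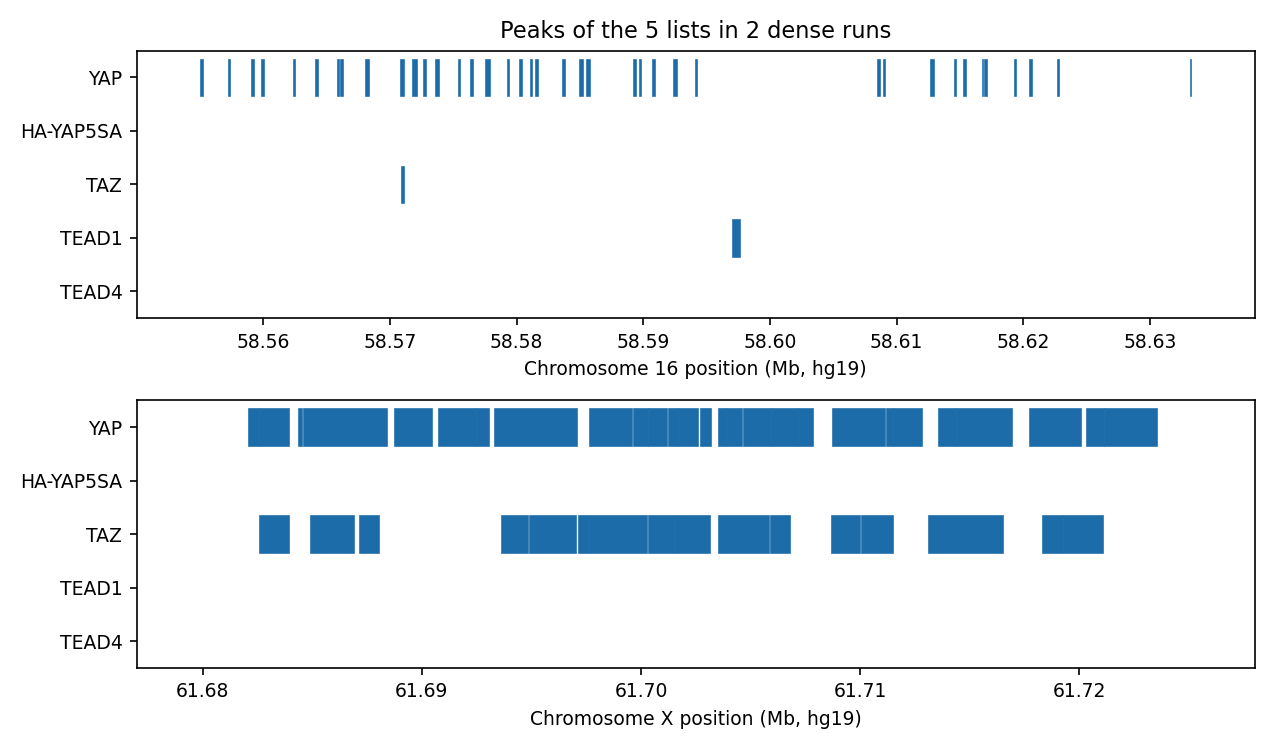
Peaks of the 5 lists, drawn to scale as blocks along the hg19 position in Mb, in a run on chromosome 16 (top) and a run on chromosome X (bottom). The 39 YAP peaks on chromosome 16 are short and separate, with 1 TAZ and 1 TEAD1 peak in the run, while on chromosome X the run holds 27 YAP and 16 TAZ peaks and no TEAD or HA-YAP5SA peak.

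Outside runs and scaffolds, a larger share of YAP peaks lay on TEAD sites. Of the 134 dispersed YAP peaks, 73 (54.5%, interval 45.7 to 63.1%) overlapped TEAD1, 67 (50%, 41.2 to 58.8%) overlapped TEAD4 and 53 (39.6%, 31.2 to 48.4%) overlapped HA-YAP5SA. In runs and on scaffolds, 19 of 320 YAP peaks (5.94%, 3.61 to 9.12%) overlapped TEAD1 and 1 overlapped HA-YAP5SA. Dispersed YAP peaks had a median width of 266 bp, against 810 bp in runs and on scaffolds. The dispersed class still held 19 YAP peaks wider than 1 kb, of which 7 overlapped TEAD1, since 3 or fewer neighbouring peaks do not make a run.

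**Figure D2:**
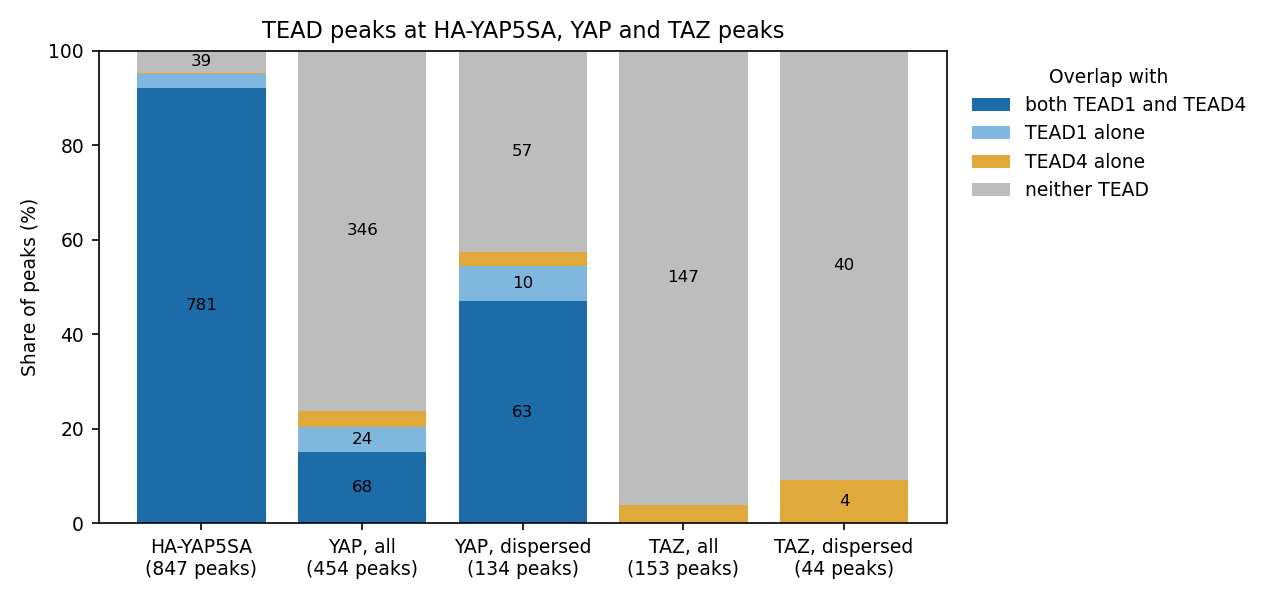
Share of peaks in percent (vertical axis) that overlapped both TEADs, TEAD1 alone, TEAD4 alone or neither, for HA-YAP5SA, YAP and TAZ, with dispersed YAP and TAZ peaks drawn apart. Numbers in the bars are peaks. Both TEADs were present at 781 of 847 HA-YAP5SA peaks, 68 of 454 YAP peaks and 63 of 134 dispersed YAP peaks.

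The second comparison set the YAP antibody against tagged YAP5SA. These lists differ in both the antibody and the form of YAP, whose effects cannot be told apart here. The sample titles do not say whether the YAP library came from cells that carried the tagged form. Only a small part of HA-YAP5SA sites had a YAP peak, 55 of 847 (6.49%). HA-YAP5SA peaks with YAP had a median score of 248 (interquartile range 178 to 463), against 112 (90.6 to 159) for the other 792 (adjusted p = 1.8e-05, two-sided permutation test over peaks). They were also wider, 372 against 218 bp (adjusted p = 1.8e-05, same permutation test). Among TEAD1 peaks, 52 of the 787 with HA-YAP5SA also had YAP (6.61%), against 28 of the 37399 without (0.0749%), an odds ratio of 94.4 (p = 6.8e-68, Fisher's exact test, two-sided). Without runs and scaffolds the odds ratio was 136 (p = 9.2e-71, Fisher's exact test). The odds ratios were not matched for the TEAD1 score. The highest decile of that score held 660 of the 787 TEAD1 peaks with HA-YAP5SA and 58 of the 80 with YAP. This split of the HA-YAP5SA list and the odds ratios were chosen after the lists had been examined.

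YAP, HA-YAP5SA, TEAD1 and TEAD4 coincided at 52 YAP peaks on 17 chromosomes or scaffolds, 51 of them outside runs and scaffolds. No site carried all 5 lists. The TEAD1 peaks at these 52 sites had a median percentile of 99.6 among TEAD1 scores (lowest 86.7), and the TEAD4 peaks a median percentile of 99.3 among TEAD4 scores (lowest 82.8). Ordered by YAP score, the chromosome 14 site described above came first. It was followed by chromosome 1 (19379002 to 19379304, YAP score 361), chromosome 1 (246598906 to 246599128, YAP score 275), chromosome 3 (101561359 to 101561757, YAP score 228) and chromosome 1 (109045650 to 109045977, YAP score 208). The sixth to the tenth were on chromosome 13 (111137885 to 111138217, YAP score 173), chromosome 12 (46888158 to 46888405, YAP score 165), chromosome 10 (96157597 to 96157856, YAP score 160), chromosome 14 (56072563 to 56072811, YAP score 141) and chromosome 2 (12164370 to 12164689, YAP score 141).

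TAZ peaks showed no overlap with TEAD1 and little with TEAD4. None of the 153 TAZ peaks overlapped TEAD1, which allows a share of up to 1.96%, and shifted TAZ peaks met TEAD1 2.28 times on average (95% of shifts 0 to 6), so that 0 overlaps was within chance. Over the 136 TAZ peaks on a chromosome or scaffold with a TEAD1 peak, the nearest TEAD1 centre lay a median of 139.8 kb away. TEAD4 was present at 6 TAZ peaks (3.92%, interval 1.45 to 8.34%), against 0.597 by chance (95% of shifts 0 to 3, adjusted p = 0.00063, shift permutation test). None of these 6 TAZ peaks overlapped TEAD1, although 97.1% of all TEAD4 peaks did. The TEAD4 peaks they met were unusually wide, with a median of 2486 bp against 351 bp for other TEAD4 peaks. HA-YAP5SA was present at 1 TAZ peak (0.654%, 0.0165 to 3.59%, adjusted p = 0.038, same permutation test). Neither overlap passed among peaks at or above the median score of their lists. TAZ also lay with YAP: 35 TAZ peaks (22.9%, 16.5 to 30.4%) overlapped a YAP peak, against 8.31 by chance (95% of shifts 7 to 10, adjusted p = 0.00014, shift permutation test). The chance share was 5.43% here and 0.610% with local shifts. Among the 101 TAZ peaks on chromosomes 1 to 22 and X, 25.7% overlapped YAP, against 0.0272% by chance. Outside runs and scaffolds this was 2 of 44 TAZ peaks (4.55%, 0.555 to 15.5%), against 0.023% by chance (adjusted p = 0.0025, shift permutation test). Part of this lower share follows from the definition of a run, which joins neighbouring YAP and TAZ peaks. The top TAZ peaks adjoined each other on chromosome X (58566358 to 58577584, score 1392, and 58577586 to 58581307, score 1031), and 9 of the 10 highest-scoring TAZ peaks lay in runs or on scaffolds. The third, on chromosome 21 (9825440 to 9827641, score 694), overlapped YAP, HA-YAP5SA and TEAD4.

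The TEAD factors were compared with each other next. Nearly every TEAD4 peak lay on a TEAD1 peak, 11835 of 12188 (97.1%, interval 96.8 to 97.4%), against 163 by chance (95% of shifts 137 to 190, adjusted p = 0.00014, shift permutation test). The centres were a median of 46 bp apart (interquartile range 21 to 85 bp). With the TEAD1 list reduced to its 12188 highest-scoring peaks, as many as TEAD4 has, 9105 TEAD4 peaks (74.7%) lay on TEAD1. In the other direction 11668 of 38186 TEAD1 peaks (30.6%) overlapped TEAD4. TEAD1 peaks with TEAD4 had a median score of 452 (281 to 718), against 136 (102 to 202) without (adjusted p = 1e-05, two-sided permutation test over peaks). The 353 TEAD4 peaks without TEAD1 had a median score of 95.6, against 166 for the others (adjusted p = 1.1e-05, same permutation test), a difference that no longer passed among TEAD4 peaks at or above the median score. The TEAD4 peak on chromosome 8 (128747932 to 128748641), with a score of 3100, was the single top 10 TEAD4 peak that did not overlap TEAD1. The highest TEAD1 scores were on chromosome 7 (55034703 to 55035819, score 3147), chromosome 14 (above) and chromosome 15 (63400049 to 63400876, score 3140). All 10 of the top TEAD1 peaks overlapped TEAD4 and 8 overlapped HA-YAP5SA. Among the top TEAD4 peaks, 8 of 10 overlapped HA-YAP5SA, including those on chromosome 3 (134044922 to 134046636, score 3100) and chromosome 1 (205270119 to 205271321, score 3100), while the peak on chromosome 5 (1326933 to 1329197, score 3100) did not.

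TEAD peaks with YAP or HA-YAP5SA had higher scores than the rest of their TEAD list. The 787 TEAD1 peaks with HA-YAP5SA had a median score of 1184 (interquartile range 802 to 1607), against 174 (112 to 318) for the others, and the 80 with YAP had a median of 1651 (527 to 2243) against 177 (113 to 332). The adjusted p was 1e-05 for each (two-sided permutation test over peaks, 100000 permutations), the smallest these permutations can give. In the TEAD4 list the medians were 534 with HA-YAP5SA and 154 without, and 1030 with YAP and 162 without (adjusted p = 1.1e-05 for each, same permutation test). TEAD1 peaks with HA-YAP5SA were also wider, 785 against 549 bp, as were those with YAP, 887 against 552 bp (adjusted p = 1e-05 for each, same permutation test). The 6 TEAD4 peaks with TAZ had a median score of 123 against 162 for the others (adjusted p = 0.43, same permutation test) and a median width of 2486 against 351 bp (adjusted p = 1.1e-05, same permutation test). Wider peaks overlap another peak more easily, so part of a width difference can come from the overlap rule. With centres within 500 bp instead, the width difference was 1533.5 bp for the 4 TEAD4 peaks then counted with TAZ. For TEAD1 peaks it was 236 bp with HA-YAP5SA and 329 bp with YAP.

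**Figure D3:**
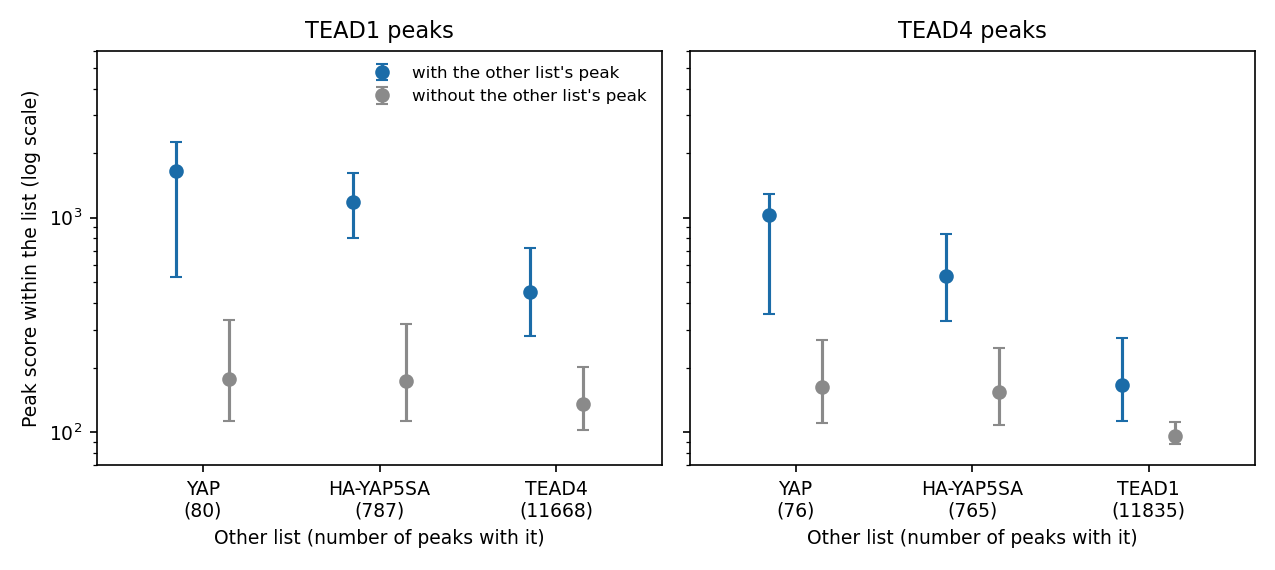
Median score with interquartile range (points and bars, log scale) of TEAD1 peaks (left) and TEAD4 peaks (right) with and without a peak of another list. Scores are compared within a list only: TEAD1 peaks with HA-YAP5SA had a median of 1184 against 174 without.

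The share of TEAD1 peaks carrying HA-YAP5SA or YAP was highest at the top of the TEAD1 list. HA-YAP5SA was present at 660 of the 3819 TEAD1 peaks in the highest score decile (17.3%, interval 16.1 to 18.5%), at 76 of 3818 in the ninth (1.99%, 1.57 to 2.49%) and at 4 of 3819 in the lowest (0.105%, 0.0285 to 0.268%). YAP was present at 58 in the highest decile (1.52%, 1.16 to 1.96%) and at 4 in the ninth (0.105%, 0.0286 to 0.268%). The share with TEAD4 went from 2.20% (1.76 to 2.72%) in the lowest decile to 97.0% (96.4 to 97.5%) in the highest. A high TEAD1 score did not always come with an HA-YAP5SA peak: of the 787 TEAD1 peaks with the highest scores, 356 (45.2%, 41.7 to 48.8%) carried one. A missing HA-YAP5SA peak can reflect the depth or threshold of that list and does not show that the protein was absent.

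**Figure D4:**
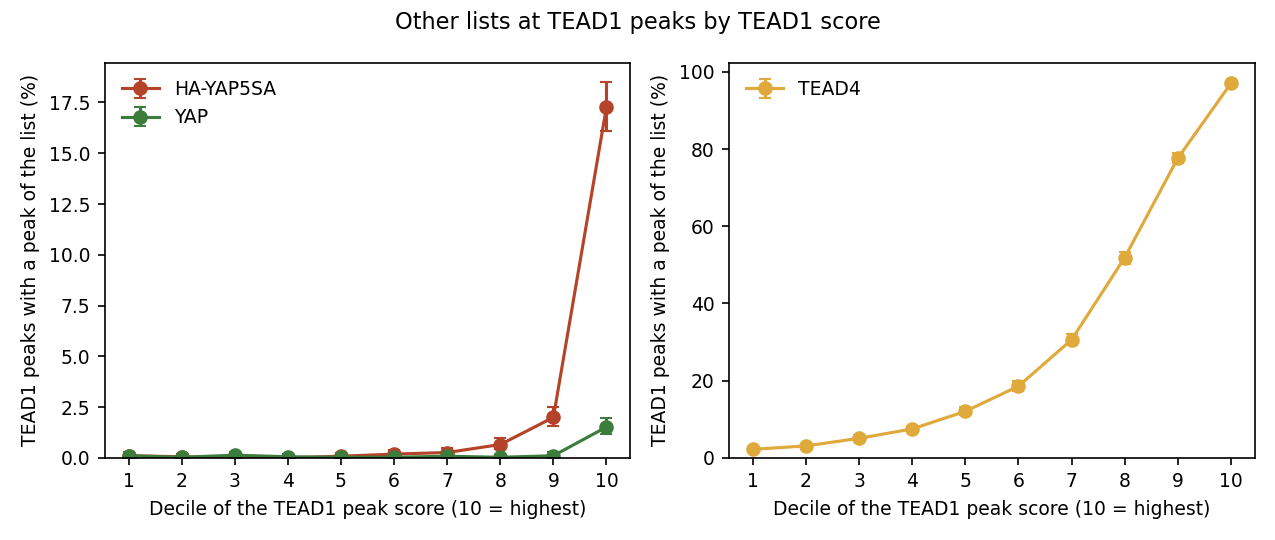
Share of TEAD1 peaks in percent, with exact 95% intervals, that overlapped HA-YAP5SA or YAP (left) and TEAD4 (right), by decile of the TEAD1 score. HA-YAP5SA was present at 17.3% of TEAD1 peaks in the highest decile and 1.99% in the ninth.

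TEAD1 sites with HA-YAP5SA were more often clustered. Another TEAD1 peak lay within the distance set for clusters for 493 of 787 TEAD1 peaks with HA-YAP5SA (62.6%, interval 59.2 to 66.0%) and for 19279 of 37399 without (51.5%), an odds ratio of 1.58 (adjusted p = 9.3e-10, Fisher's exact test). With TEAD4 the share was 58.1%, against 49.0% without (adjusted p = 2.7e-60, Fisher's exact test). TEAD4 was present at 97.0% of the TEAD1 peaks with HA-YAP5SA, and the comparison was not matched for TEAD4 or the TEAD1 score. Clustered peaks count each other as neighbours, so the tests treat dependent peaks as independent. For YAP the shares were 61.3% (49.7 to 71.9%) of 80 peaks and 51.8% of the others, a difference that did not pass the test (p = 0.094, Fisher's exact test). It passed with a distance of 5 kb and vanished with 50 kb. The splits by HA-YAP5SA and TEAD4 were added after the lists had been examined.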

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

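Each result was recomputed with 1 choice changed at a time; the tests without runs and scaffolds, with other gaps in a run, of clusters by HA-YAP5SA and TEAD4, and of HA-YAP5SA peaks with YAP were chosen after the results were seen. Of 185 recomputed values for 42 results, 168 kept their direction and their side of the threshold, or stayed within the interval of a share. The overlaps of HA-YAP5SA, YAP and TEAD4 with TEAD1, of HA-YAP5SA and YAP with TEAD4, of YAP with HA-YAP5SA and of TAZ with YAP passed under every alternative run. The shares of HA-YAP5SA peaks on TEAD1 and on TEAD4 stayed between 91.7 and 96%, while other shares moved under some alternatives. With both lists cut to scores at or above the median, the shares were 9.25% for YAP on TEAD1, 5.29% for YAP on TEAD4, 3.96% for YAP on HA-YAP5SA and 35.1% for TAZ on YAP. TEAD4 on TEAD1 was 74.7% with as many TEAD1 as TEAD4 peaks. TAZ on YAP was 13.1% with centres within 500 bp, and without runs and scaffolds YAP on TEAD1, TEAD4 and HA-YAP5SA was 54.5, 50 and 39.6% and TAZ on YAP 4.55%. The overlap of TAZ with TEAD4 was 1.30% among the peaks with scores at or above the median of each list and no longer passed (adjusted p = 0.23, shift permutation test). The single TAZ peak on HA-YAP5SA stayed at 0.654% within 1 kb but no longer passed (adjusted p = 0.088, shift permutation test). Among the 77 TAZ peaks with scores at or above the median this share was 0%. It counted as a reversal, but the chance share was 0.0177%, so a count of 0 is what chance gives. With YAP, HA-YAP5SA and TAZ peaks at or above their median scores, 7.05% of YAP peaks lay on both TEADs, 8.37% on TEAD1 alone and 6.17% on TEAD4 alone, and for HA-YAP5SA these were 94.8%, 1.18% and 0%. Without runs and scaffolds, 47.0% of YAP peaks lay on both TEADs and 42.5% on neither, and 9.09% of TAZ peaks lay on TEAD4 alone and 90.9% on neither. Within the TEAD4 peaks at or above the median score, those with TEAD1 exceeded those without by 57.8 score units, no longer past the threshold, and their median width was lower by 58 bp (with minus without, -58 bp), a reversal. The difference in clustering of TEAD1 peaks with and without YAP was 11.7 percentage points at 5 kb, past the threshold, and -0.077 points at 50 kb, a reversal. The causes were not tested. The number of dispersed YAP peaks was 142 with a largest gap of 10 kb in a run and 128 with 50 kb. The comparisons with promoters, motifs and gene lists, and their alternatives, were not run, because no genome or annotation of the build was used. No paired analysis was possible because each antibody has 1 library. Depth is unknown for every list, so a missing peak is not evidence that a factor was absent.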

Other observations

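The tests in this part were chosen after the lists had been seen, except the prediction on TEAD4 within TEAD1 score deciles and the one on TEAD peak density in the chromosome 16 run, which were written down before their results; the 100 score classes were added afterwards. HA-YAP5SA was spread unevenly over TEAD1 sites of different chromosomes. It was present at 3.63% of TEAD1 peaks on chromosome 14 (47 of 1293, exact 95% interval 2.68 to 4.80%, adjusted p = 0.0015), 2.95% on chromosome 11 (61 of 2067, 2.26 to 3.77%, adjusted p = 0.024) and 2.90% on chromosome 1 (117 of 4037, 2.40 to 3.46%, adjusted p = 0.0015), by Fisher's exact test against the other chromosomes over 23 chromosomes. It was present at 1.16% on chromosome 2 (38 of 3290, 0.819 to 1.58%, adjusted p = 0.0011), 1.13% on chromosome 6 (24 of 2125, 0.725 to 1.68%, adjusted p = 0.0069) and 1.31% on chromosome 4 (30 of 2293, 0.884 to 1.86%, adjusted p = 0.030), same exact test. These shares were not adjusted for the TEAD1 score, TEAD4 or copy number, and the cause of the differences was not tested. The densest 1 Mb windows of TEAD1 peaks were on chromosome 1 (94000001 to 95000000, 63 peaks), chromosome 15 (39000001 to 40000000, 62 peaks) and chromosome 1 (172000001 to 173000000, 60 peaks), against a median of 12 over windows with a peak. HA-YAP5SA was present at 3, 4 and 3 of the TEAD1 peaks in these windows.

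The 39 HA-YAP5SA peaks with no TEAD peak were narrower than the 808 others, 145 against 226 bp (adjusted p = 0.0023, two-sided permutation test over peaks), with median scores of 105 and 114 (adjusted p = 0.31, same permutation test). Of these 39, 5 lay in the first 100 kb of a chromosome, among them the third-ranked HA-YAP5SA peak, at the start of chromosome 5, against 1 of the 808 others (p = 9.3e-07, Fisher's exact test). The test counts adjoining peaks on chromosome 12 (95421 to 95566 and 95594 to 95741) as separate. Chromosome ends were not tested.

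The first pattern is that YAP peaks off TEAD1 lie in dense runs and on scaffolds. Read pile-up in sequence that behaves alike in the YAP and TAZ libraries may account for part of it. With runs taken from the YAP list alone (22 runs), 45 of 309 YAP peaks in runs or on scaffolds (14.6%) carried a TAZ peak. The share elsewhere was 3 of 145 (2.07%, p = 1.2e-05, Fisher's exact test). The chromosome X run (61682072 to 61723527) held 19 of the 45, and without it the share was 9.22% (p = 0.0041, Fisher's exact test). With each run or scaffold as 1 unit, 7 of 26 held any such peak. The mean share was 11.6%, against 1.88% over 124 dispersed units (p = 0.0085, two-sided permutation test). These tests cannot separate pile-up from binding that the paralogues YAP and TAZ share. Wider peaks also meet a TAZ peak more easily. With runs of YAP or TAZ peaks, the median YAP width was 810 bp in runs and on scaffolds and 266 bp elsewhere. Those runs held 10 TEAD1, 10 TEAD4 and 0 HA-YAP5SA peaks. YAP binding away from TEAD stays open: HA-YAP5SA was present at 1 of these 309 (0.324%), against 53 of 145 elsewhere (36.6%), but the control library behind each list is not known, and a control rich in these sequences would remove such peaks from the list.

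The second pattern is the run on chromosome 16 (hg19 58555042 to 58633252), whose 39 YAP peaks are short and separate. Their median width was 224 bp, against 900 bp for the other YAP peaks in runs or on scaffolds. A TAZ run on chromosome 1 (52924014 to 52975384) has a similar form, with 10 TAZ peaks of 93 to 250 bp and no peak of another list. A DNA copy of a spliced transcript in the library could give such peaks at exons, but exons were not searched and this cannot be told apart from other sources. Raised copy number of the stretch is also undecided: it held 1 TEAD1 or TEAD4 peak, against 1.80 expected from the 500 kb on either side, too few to decide. No biological explanation of this run was tested.

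The third pattern is that HA-YAP5SA lies at high-scoring TEAD1 peaks. Classes of the TEAD1 score did not account for all of it. Within deciles of the TEAD1 score, TEAD1 peaks with TEAD4 had a common odds ratio of 5.75 for HA-YAP5SA (95% interval 3.42 to 9.65, Mantel-Haenszel). With 100 score classes, of which 51 were informative, it was 4.04 (2.40 to 6.81). Only 24 TEAD1 peaks with HA-YAP5SA lacked TEAD4, and TEAD4 presence itself rose with the TEAD1 score. The test therefore cannot separate a role of TEAD4 from site strength that the TEAD1 score measures imperfectly. That only the strongest sites pass the threshold of a weaker library stays open: the share was 17.3% in the top decile against 2.06% of all TEAD1 peaks, but the lowest deciles held too few HA-YAP5SA peaks to show a steady rise, and depth is unknown. No biological explanation of this pattern was tested.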
